A study of Mus musculus with 59 samples.

How the data were processed

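The data were RNA-seq libraries from Tcf7-knockout scid.adh cells, a mouse thymic lymphoma line, and from primary Tcf7-deficient mouse progenitors. All were transduced with TCF-1 constructs or an empty vector. Per the labels' protocols, cells of the line were sorted 72 h after transduction, and primary cells were sorted as DN1 or DN2 after 7 days of co-culture on OP9-DLL1 stroma. The gates, per the labels' protocols, were CD45+ c-Kit high CD44 high CD25 low for DN1 and CD45+ c-Kit low CD44 low CD25 high for DN2, although the labels' source name calls the DN2 cells CD44+. Libraries were made with the SMARTer Stranded Total RNA-Seq Kit version 2 (Pico input) and read as pairs of 38 and 37 bp on a NextSeq 550, per the labels' protocols. The molecule label reads genomic DNA, which the protocol and the values contradict, so the libraries were taken as RNA.

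Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.0a and HTSeq 0.6.1 was used. The deposited values are read counts per gene in the layout of STAR's gene count tables, with the authors' counts given ignoring strand, for the forward strand and for the reverse strand. No normalization by the authors was found in the values, which are whole numbers. The reverse-strand counts were used here, because the forward-strand counts held 5.44% to 8.56% of the stranded gene reads in the cell line and 4.88% to 6.97% in primary cells. All 58 libraries list the same 45706 genes in the same order, of which 45143 were matched to a symbol. The annotation release is not stated by the submitters, and positions and symbols were taken from GENCODE M21 for GRCm38.

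Of the 59 samples given for this work 58 were used. The file of DN1 L1d replicate 1, library 3, stops early after 14312 complete genes and 1.93 M reads, so that library was left out. The design written before the data were examined had named 45 primary libraries, and 44 were used. The labels of primary libraries carry a number with the letter B and one with the letter T. T was read as libraries made from the same B replicate, and these were summed, which gave 2 replicates per group and 16 in all, from 29 DN1 and 16 DN2 deposited libraries. The meaning of these letters is not stated, and the fit with each T library as its own replicate is among the alternatives. DN2 cells with EV or HMGd were not analysed here.

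Cell line libraries held 3.82 to 9.48 M reads in genes and primary libraries 4.17 to 18.96 M. The share of reads not counted in genes was 65.9% to 73.9% in the cell line and 56.1% to 68.6% in primary cells. Ribosomal RNA genes took 17.1% to 32% of the counted reads in the cell line and 15.4% to 24.23% in primary cells. Between 14567 and 16550 genes had a read per cell line library, and 15816 to 19150 per primary library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A group with 0 counts was given a floor of 3 counts over the group, and fold changes against it are written as at least that fold.

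Counts were tested with edgeR 4.0.16 in R 4.3.3, in a fit of the 14 cell line libraries (7 residual degrees of freedom) and a fit of the 16 summed primary replicates (8 residual degrees of freedom). Genes with low counts were removed with edgeR's filterByExpr at its default settings, which left 10939 genes in the cell line and 15010 in primary cells. Libraries were scaled by TMM, with factors of 0.86 to 1.09 in the cell line and 0.888 to 1.14 in primary cells. Each comparison used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of its fit and a threshold of 0.05, without a block for replicate number. Fold changes were computed with a prior count of 0.125. CPM values are TMM-scaled, and their spread is the SD of 2 replicates. The common biological coefficient of variation was 4.48% between cell line replicates, 9.2% between B replicates of primary cells and 4.93% between T libraries of the same B replicate.

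There were 26 comparisons, made of 11 in the cell line, 8 within DN1, 3 within DN2, 3 of DN2 against DN1 and 1 interaction. The comparisons, the gene lists, the naming rule and all alternatives but 1 were fixed before the data were examined. The 19 lists were T lineage, Notch response, progenitor, type 2 and type 3 innate lymphoid, natural killer and cytotoxic, myeloid, mast cell and basophil, dendritic, B lineage, erythroid and megakaryocyte, OP9 stroma, proliferation, Wnt response, later T cell, gamma-delta T, interferon response, p53 response, early stress and mitochondrial genome. Lists with fewer than 3 measured members in a fit were not tested there, which left out the mast cell, stroma and gamma-delta lists in the cell line. Each list was tested against the other genes with limma's camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 461 list tests. It was tested again with the correlation estimated from the residuals, where the lowest adjusted p of any list was 0.0977, so no list call holds with an estimated correlation. A list is given as counts of members called over all genes and adjusted over the list alone.

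Genes were named by a fixed rule. Tcf7 was always named. In 6 main comparisons (WT against EV and DL1 against WT in the line, P45 against EV and L1d against P45 in DN1, L1d against P45 in DN2, and DN2 against DN1 with P45) the rule took the 8 largest rises and 8 largest falls past the threshold with at least 5 CPM in the higher group and no overlap of replicates, and up to 4 members with the smallest p per list. In the others it took 3 rises, 3 falls and 2 members per list. Predicted genes, antigen receptor segments other than constant regions and pseudogenes were left out of the rises and falls. Col1a1, Uty and Gm42418 fall outside the rule and were chosen after their values were seen, as was the level of Bnip3 with DHMG, which the rule names only in other comparisons. The text prints a part of the genes that the rule picked, and 2 genes were left out of it because they are withheld for evaluation.

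Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each T library as a replicate, a fit of the same stage alone, fits without CL_DHMG or with only the EV, WT and DHMG libraries, each replicate left out in turn, limma's fry for lists, and, added after the data were seen, counts that ignore strand. Where a replicate was left out, the remaining sample of its group was assumed to vary like the other groups. For constructs that share EV libraries, 20 simulations of unchanged groups gave the correlation and covariance that shared controls produce. Tcf7, which the constructs themselves raise, was kept among the genes there. The steps were tested on simulated data with 200 changed genes. In the simulated WT against EV comparison over 10939 genes, 83% of genes changed 2-fold and 97% of those changed 4-fold were called, with 9 calls among unchanged genes. Over 15010 genes these values were 62%, 84% and 6 for L1d against P45 in DN1 cells and 64%, 86% and 13 in DN2 cells, and 0 of 19 random lists were called in each. The simulated genes were drawn independently, so this cannot show false list calls that come from correlated genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to read the files and draw the figures.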

Results

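RNA was sequenced from 58 mouse libraries that were used here, 14 from a cell line and 44 from primary cells. The cell line was scid.adh, a thymic lymphoma line that resembles early T cells, with its Tcf7 gene knocked out. Tcf7 encodes TCF-1, a transcription factor of early T cell development. Cells of the line received 1 of 7 retroviruses. These were an empty vector (EV), wild-type TCF-1 (WT), constructs named DL1, DL2, DL6 and DL7, read here as deletions of the segments L1, L2, L6 and L7, and DHMG, read as lacking the HMG box that binds DNA. The cells were sorted 72 h after transduction, with 1 library for each of 2 replicates per group and 3.82 to 9.48 M reads counted in genes per library.

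The primary cells came from bone marrow progenitors lacking Tcf7 that received EV, P45 (the name that the cell line labels give the wild-type form), L1d, L7d or HMGd, and grew for 7 days on OP9-DLL1 stroma, which presents a Notch ligand. They were sorted into DN1 cells, the earliest progenitors, and DN2 cells, the next stage, which carry CD25. DN1 cells were used with all 5 constructs and DN2 cells with P45, L1d and L7d, while DN2 cells with EV or HMGd were not analysed here. Libraries with the same replicate number after the letter B were summed, giving 2 replicates in each of 8 groups with 9.06 to 34.39 M reads in genes per replicate. Nothing in the labels says that replicates are separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Levels below are counts scaled to the library size (CPM, with TMM factors) as mean ± SD. Fold changes are given with the standard error (SE) of their log2, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For each gene named as one of the largest changes, every replicate of 1 group lay above every replicate of the other.

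Tcf7 RNA was read first, as counts over the whole gene, which show whether Tcf7 RNA was added but not which segment a construct lacks. In the cell line with EV, Tcf7 stood at 557 ± 9.86 CPM (SD, n = 2), so the altered gene still gave counted reads. The level was 1765 ± 64.2 CPM (SD, n = 2) with WT, 2540.3 ± 166 with DL1, 2019 ± 59.4 with DL2, 2547 ± 43.3 with DL6, 1925 ± 14.7 with DL7 and 3746 ± 26.5 with DHMG. In DN1 cells Tcf7 rose from 3.79 ± 0.661 CPM with EV to 637 ± 16.2 with P45, 729 ± 49.1 with L1d, 842 ± 59.1 with L7d and 877 ± 122 with HMGd (SD, n = 2 each). DN2 cells held 719 ± 5.86 CPM with P45, 845 ± 50.7 with L1d and 1075 ± 46.1 with L7d (SD, n = 2). Tcf7 was higher with every construct than with its EV control, with adjusted p = 3.85e-29 for WT in the cell line and 4.6e-14 for P45 in DN1 cells.

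**Figure D1:**
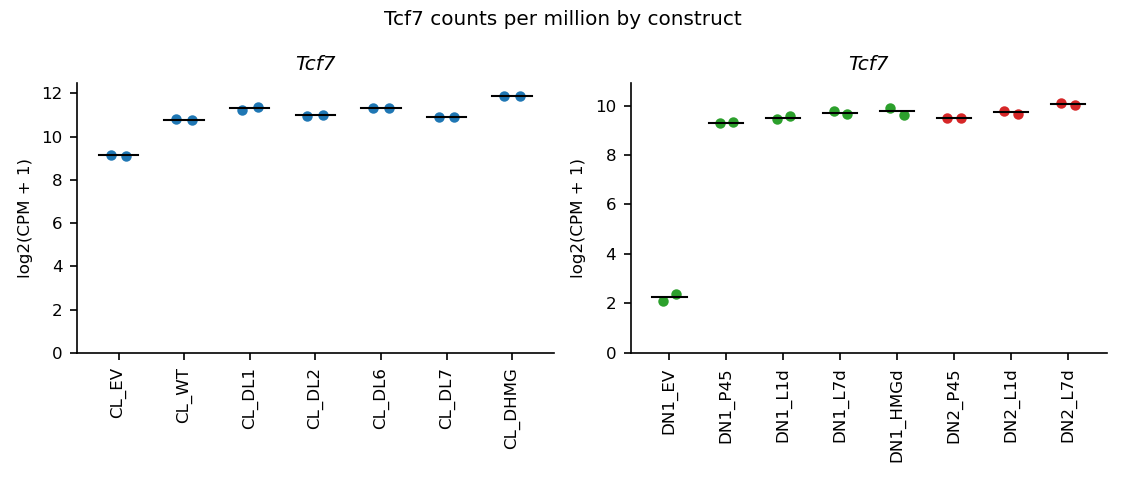
Each point is 1 replicate's Tcf7 level as log2(CPM + 1) on the vertical axis, the groups stand along the horizontal axis, and the black line is the mean of the 2 replicates; cell line groups are in one panel and primary groups in the other. The EV points lie below all construct points in both panels, at a mean of 557 CPM in the cell line and 3.79 CPM in DN1 cells.

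What wild-type TCF-1 changes in a T cell line without Tcf7 was read from WT against EV. The largest rises were in Ighm, the heavy chain of immunoglobulin M, at 18.2 ± 2.83 CPM against 1.5 ± 0.776 (SD, n = 2, 12.4-fold, SE 0.29, adjusted p = 2.95e-13). Ace, the angiotensin-converting enzyme, was at 21.4 ± 0.633 against 2.0 ± 0.421 (10.5-fold, SE 0.27, adjusted p = 2.67e-13). Cdh1, which encodes E-cadherin, rose 7.03-fold and Ifi202b, an interferon-inducible gene, 5.27-fold. The largest falls were in Nfib, a transcription factor, 17.6-fold lower at 0.326 ± 0.46 CPM, and Zcchc14, 16-fold lower. Ndrg1, a gene known to respond to low oxygen, was 15.6-fold lower at 3.76 ± 0.21 CPM against 58.6 ± 2.41 (SE 0.15, adjusted p = 2.79e-25). Cpa3, a mast cell protease, fell 8.36-fold from 40.3 ± 0.691 CPM, Itgae, the integrin chain CD103, 6.11-fold from 17.4 ± 1.01, and Cyp11a1, the first enzyme of steroid synthesis, 5.14-fold from 30.8 ± 0.0966.

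The T lineage list held 28 measured members, of which 4 were higher, 12 lower and 12 not called (5 and 12 adjusted over the list alone). Bcl11b, a factor of T cell commitment, fell from 587 ± 8.88 to 419 ± 2.75 CPM, and Il2ra, which encodes CD25, from 1008 ± 22.5 to 638 ± 3.98 (SD, n = 2). The list's camera adjusted p was 9.17e-05 downward, and the adjusted p was 0.159 with an estimated correlation. Among 8 genes of type 2 and type 3 innate lymphoid cells, 5 were lower and 3 not called, the same 5 when adjusted over the list alone. Rora fell 3.04-fold, Id2 1.46-fold and Il17rb 1.61-fold (camera adjusted p = 0.00047, adjusted p = 0.134 with an estimated correlation). Of 7 mitochondrially encoded genes 6 were lower and 1 was not called, mt-Nd4 by 1.47-fold (6 adjusted over the list alone, camera adjusted p = 4.01e-08, adjusted p = 0.178 with an estimated correlation). Mitochondrial ribosomal RNA took 14.87% and 15.46% of the counted reads with WT against 16.49% and 16.61% with EV. In the proliferation list 7 of 26 genes were higher, among them Cdc20 and Birc5, and 2 were lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.174 with an estimated correlation).

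Notch response genes moved both ways, with 3 of 10 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.305, and adjusted p = 0.587 with an estimated correlation). Nrarp, a Notch target, rose from 173 ± 11 to 313 ± 3.86 CPM (SD, n = 2) and Notch1 rose 1.22-fold, while Notch3 fell 1.22-fold. Interferon response genes did too, with Ifi203 2.27-fold higher and Mx1 2.57-fold lower among 2 higher and 3 lower of 9, with a median of 0.05, a mean of -0.13 and a downward test (camera adjusted p = 0.896, adjusted p = 0.92 with an estimated correlation). Later T cell genes had 2 higher and 5 lower of 12, with Slamf6 2.1-fold higher and Arpp21 1.66-fold lower (camera adjusted p = 0.54, adjusted p = 0.644 with an estimated correlation). For 5 B lineage genes the median log2 fold change was -0.38 but the mean was 0.22 and the test pointed upward (camera adjusted p = 0.684, adjusted p = 0.784 with an estimated correlation), since Ighm rose while Pou2af1 fell 2.38-fold. In all, 1348 genes were higher and 1374 lower among 10939 tested, 238 of them by at least 2-fold. The total of 2722 was 1757 with DESeq2, and it was also lower with any 1 of the 4 libraries left out. Each gene named here as changed kept its call in all 4 cases, but these are a part of the rule's picks, and other picks lost theirs.

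**Figure D2:**
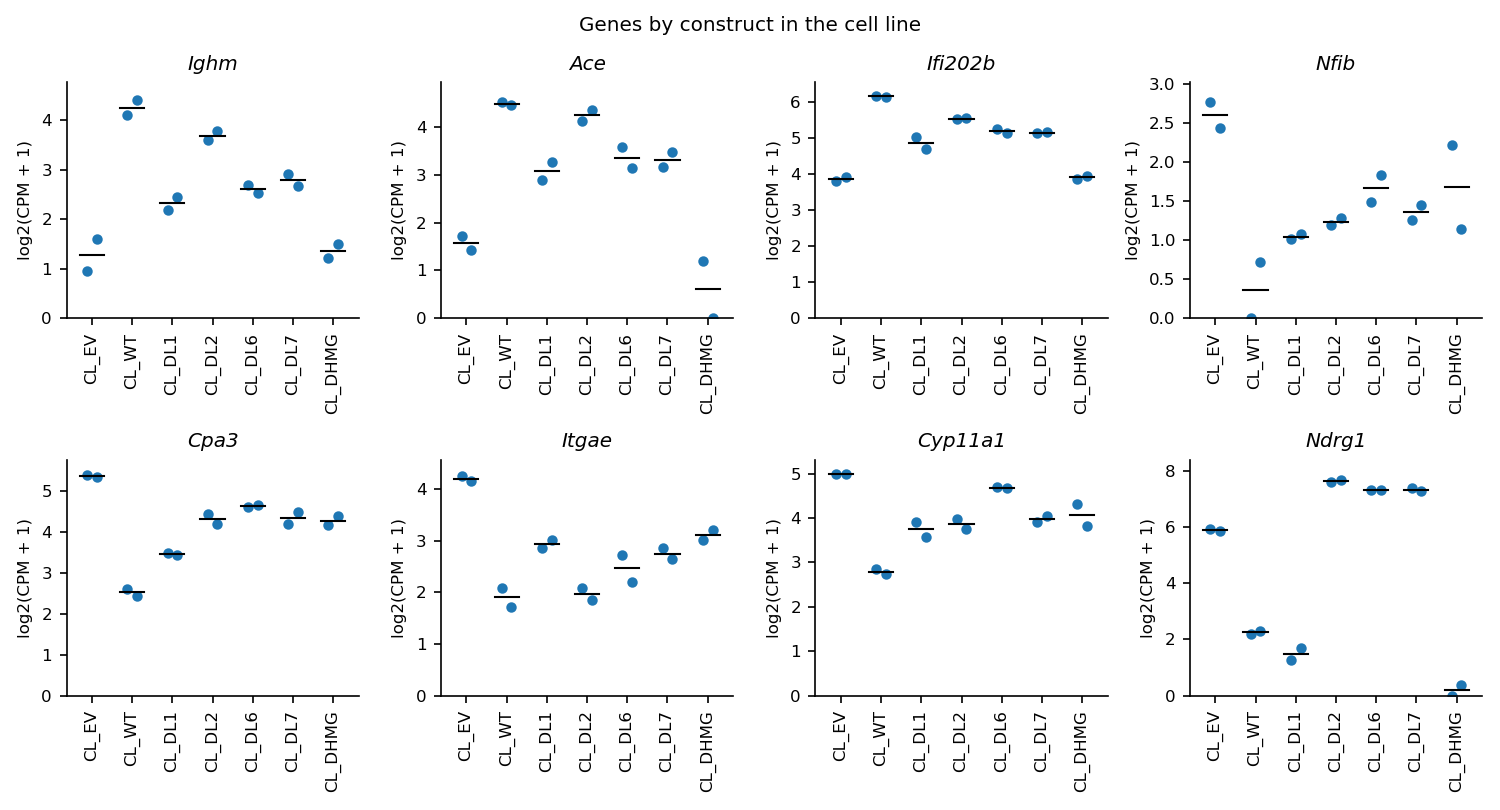
Each panel shows 1 gene in the cell line as log2(CPM + 1) on the vertical axis for the 7 groups on the horizontal axis; points are replicates and black lines are means of 2 replicates. Ighm and Ace are higher with WT (18.2 and 21.4 CPM) than with EV (1.5 and 2.0 CPM), and Ndrg1 is higher with DL2, DL6 and DL7 (199, 158 and 160 CPM) than with EV (58.6 CPM).

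Whether segment L1 is needed for these effects was asked by comparing DL1 with WT. Several genes that WT had raised were lower with DL1. Both comparisons use the same WT libraries, so WT values that are high by chance would favour both results. Ighm at 4.0 ± 0.614 CPM (SD, n = 2) fell 4.61-fold (SE 0.24, adjusted p = 2.85e-09) and Ace at 7.55 ± 1.6 fell 2.93-fold (SE 0.21, adjusted p = 5.79e-07). Ifi202b at 28.4 ± 4.57 fell 2.46-fold (SE 0.11, adjusted p = 1.59e-12). Ptprt, a receptor phosphatase, fell 2.23-fold. Among the rises, Ahnak, a very large scaffold protein, went from 6.78 ± 0.617 to 22.7 ± 0.551 CPM (3.3-fold, SE 0.17, adjusted p = 4.14e-10). Iqgap2 rose 2.9-fold and Cyp11a1 2.14-fold. Tcf7 itself was 1.44-fold higher with DL1 (adjusted p = 1.8e-11).

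Of 28 T lineage genes 10 were higher with DL1, 2 lower and 16 not called (11 and 5 adjusted over the list alone). Bcl11b stood at 562 ± 56.3 against 419 ± 2.75 CPM, Il2ra at 838 ± 69.6 against 638 ± 3.98 and Gata3, a T lineage transcription factor, at 214 ± 27.4 against 159 ± 7.31 (SD, n = 2, all called). The camera adjusted p was 0.00123 upward, with an adjusted p of 0.179 with an estimated correlation. Notch response genes had 4 higher and 1 lower of 10 (6 and 1 adjusted over the list alone), with Dtx1 1.29-fold and Notch3 1.28-fold higher (camera adjusted p = 9e-04, adjusted p = 0.178 with an estimated correlation). Of 4 measured progenitor genes, Sox4 rose 1.41-fold and Zfpm1 1.3-fold, the same 2 when adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.233 with an estimated correlation). All 7 mitochondrially encoded genes were lower, with mt-Nd1 1.29-fold lower, and 7 were called adjusted over the list alone (camera adjusted p = 1.01e-08, adjusted p = 0.175 with an estimated correlation). Mitochondrial ribosomal RNA also took less of the counted reads, 10.75% and 9.85% with DL1 against 14.87% and 15.46% with WT. For the 5 B lineage genes the median was 0.17, the mean -0.36 and the test downward, with Ighm and Cd24a lower (camera adjusted p = 0.0197, adjusted p = 0.201 with an estimated correlation). In total 736 genes were higher and 441 lower, 48 of them by at least 2-fold. The total of 1177 fell most when either WT replicate was left out. The genes named here as changed kept their calls with any 1 of the 4 libraries left out, but they are a part of the rule's picks, and other picks lost theirs.

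How far each shortened construct changed the same genes as WT was read from all constructs against EV. Ace rose with every segment deletion, 3.57-fold with DL1, 8.71-fold with DL2, 4.57-fold with DL6 and 4.32-fold with DL7. It was 0.652 ± 0.922 CPM with DHMG (SD, n = 2), 29.8-fold lower than with WT. Ighm stood at 11.9 ± 1.12 CPM with DL2, 5.12 ± 0.466 with DL6, 5.97 ± 0.816 with DL7 and 1.56 ± 0.368 with DHMG (SD, n = 2). Its call against EV ended without EV replicate 1 for DL1, DL6 and DL7 (adjusted p = 0.275, 0.279 and 0.0618) and without DL6 replicate 1 for DL6 (adjusted p = 0.0752). Itgae fell 5.85-fold with DL2, 3.79-fold with DL6 and 3-fold with DL7. Nrarp rose 1.8-fold with DL1, 1.85-fold with DL2, 1.51-fold with DL6, 1.39-fold with DL7 and 1.34-fold with DHMG. Genes called against EV numbered 641 higher and 560 lower with DL1, 258 and 296 with DL2, 77 and 87 with DL6, 171 and 133 with DL7, and 1054 and 817 with DHMG. The total for DL1 (1201) was 466 without EV replicate 1 and 511 without EV replicate 2. With any 1 of their 4 libraries left out the totals were 235 to 277 for DL2, 50 to 62 for DL6, 95 to 135 for DL7 and 1067 to 1226 for DHMG.

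Each construct's change over all 10939 genes was also set against that of WT, less what 20 simulations of unchanged groups against the shared EV libraries gave. The covariance left was set against the WT variance of 0.158 less the 0.0469 that unchanged groups gave. It was 58.4% of that difference for DL1, 52.3% for DL2, 18% for DL6, 11.3% for DL7 and 50.2% for DHMG. The covariance was 0.0889 for DL1 (0.0241 simulated), 0.0822 for DL2 (0.0243), 0.0442 for DL6 (0.0243), 0.0367 for DL7 (0.0242) and 0.0796 for DHMG (0.024). Across genes, which are not independent replicates, Pearson's r with the WT change was 0.66 for DL1 (0.51 simulated), 0.62 for DL2 (0.48), 0.42 for DL6 (0.5), 0.34 for DL7 (0.52) and 0.4 for DHMG (0.43). DL1 shared 413 higher and 406 lower genes with WT, where independent lists would share 79 and 70.3. The 2 EV libraries were not split, since each part would hold 1 library, so part of these excesses may come from the shared controls. For DL6, DL7 and DHMG, r lay below its simulated value, while their covariances lay above the simulated ones. A change particular to a construct lowers r, so the low r does not show less likeness to WT than unchanged groups have. A difference from EV between cultures that WT and a construct have in common would also count toward these shares. They are thus no measure of a kept wild-type effect alone.

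Among gene lists, Notch response genes with DL1 had 5 of 10 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 9.8e-07, adjusted p = 0.134 with an estimated correlation). T lineage genes with DL2 had 2 higher and 8 lower of 28 (2 and 11 adjusted over the list alone, camera adjusted p = 0.00044, adjusted p = 0.174 with an estimated correlation). Of the mitochondrially encoded genes, 7 of 7 were lower than in EV with DL1 and 6 with DHMG, whereas 5 were higher with DL7. The tests gave camera adjusted p = 2.58e-41, 4.52e-06 and 6.89e-09 (adjusted p = 0.0977, 0.233 and 0.174 with an estimated correlation). These constructs were not compared with each other directly. Mitochondrial ribosomal RNA took 10.75% and 9.85% of counted reads in the DL1 libraries, 14.99% and 15.05% with DHMG, 16.49% and 16.61% with EV and 19.06% and 18.26% with DL7. A shift of whole libraries is thus not told apart from a change in these genes. Against WT, Ndrg1 was 52.8-fold higher with DL2, 42-fold with DL6 and 42.8-fold with DL7, and Zcchc14 was 7.37-fold, 12.2-fold and 6.9-fold higher. Calls against WT were 750 higher and 496 lower for DL2, 1240 and 1114 for DL6, 1690 and 1641 for DL7 and 1007 and 611 for DHMG. Their totals with 1 library left out were 596 to 763 for DL2, 1376 to 1492 for DL6, 2152 to 2465 for DL7 and 835 to 1026 for DHMG. The DHMG libraries also stood apart in other genes, with Kdm5d on the Y chromosome at 0.652 ± 0.922 CPM against 11.9 ± 1.19 in EV. The 5S ribosomal RNA gene n-R5s136 was 41.1-fold higher, and ribosomal RNA genes took up to 32% of counted reads against 17.1% in the lowest cell line library.

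**Figure D3:**
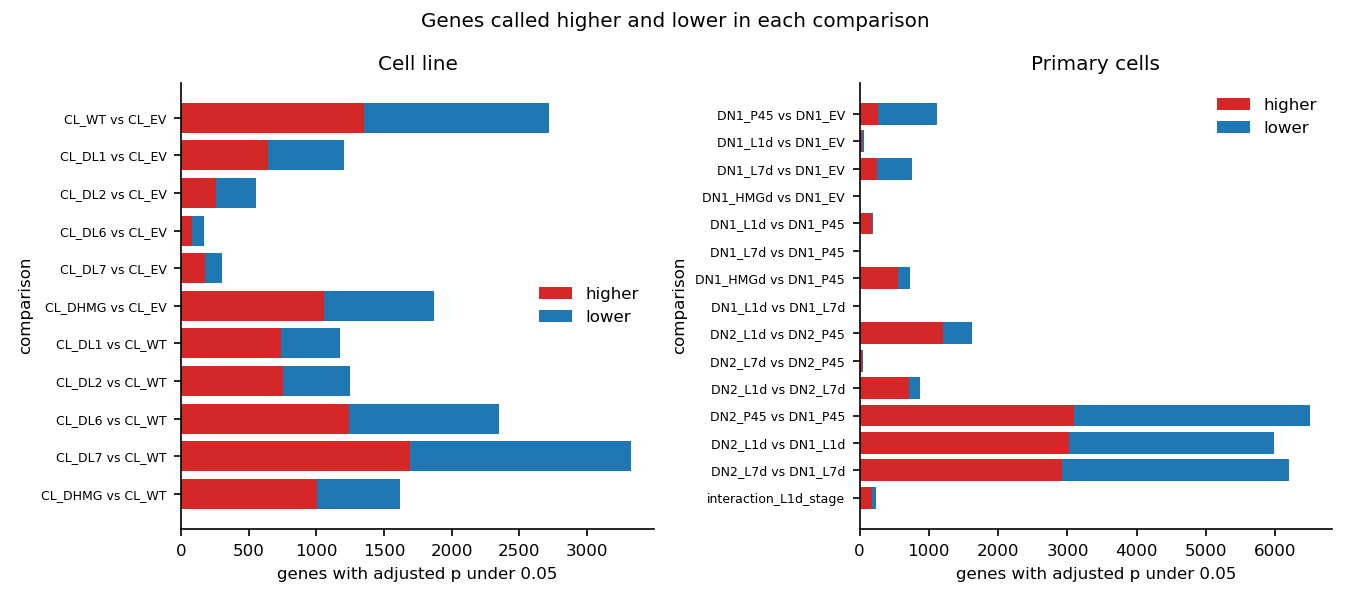
Bars give the number of genes with an adjusted p under 0.05 on the horizontal axis for each comparison on the vertical axis, split into higher (red) and lower (blue) in the first-named group; cell line comparisons are in one panel and primary ones in the other. The longest bars are those of DN2 against DN1 cells (6493 genes with P45), and those of HMGd against EV and of L7d against P45 in DN1 cells hold 1 gene each.

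What wild-type TCF-1 changes in cells of the DN1 sort was read from P45 against EV. These bulk libraries held much RNA of granulocyte genes and do not resolve which cells carry it. A different mix of cells can thus not be told apart from a change within cells, here and in the other DN1 comparisons. Enpp2, which encodes autotaxin, rose from 0.211 ± 0.0327 to 5.91 ± 0.482 CPM (SD, n = 2, 26.8-fold, SE 0.42, adjusted p = 6.88e-06). Fgf3, a fibroblast growth factor, rose 8.39-fold to 18.8 ± 2.03 (SE 0.3, adjusted p = 1.62e-05), Podxl 6.58-fold and Tek, an angiopoietin receptor, 6.21-fold. A pair of surface molecules of T cells rose as well, Cd5 by 5.74-fold to 5.88 ± 0.393 CPM and Cd6 by 5.25-fold to 21.4 ± 0.476. The Wnt target Axin2 went from 0.469 ± 0.134 to 2.71 ± 0.0883 CPM (5.86-fold, SE 0.28, adjusted p = 3.85e-05). The largest falls included Retnlg, a neutrophil gene, 8.95-fold, Prss34, a basophil protease, 8.62-fold, and Epx, eosinophil peroxidase, 6.62-fold from 64 ± 31.7 CPM.

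Of 36 myeloid genes 0 were higher, 14 lower and 22 not called (15 lower adjusted over the list alone). Itgam, the integrin chain CD11b, went from 1219 ± 31.8 to 451 ± 48.9 CPM (SD, n = 2), and Camp, an antimicrobial peptide of neutrophils, from 484 ± 13.4 to 123 ± 21.5. The gelatinase Mmp9 fell from 181 ± 11.2 to 31.3 ± 4.32, and Ly6g from 17 ± 0.579 to 2.54 ± 0.403. The camera adjusted p was 1.37e-07, and the adjusted p was 0.409 with an estimated correlation. Mast cell and basophil genes had 1 higher and 6 lower of 23 (1 and 7 adjusted over the list alone). Hdc, which makes histamine, was 2.41-fold and Alox5 2.58-fold lower (camera adjusted p = 0.000133, adjusted p = 0.375 with an estimated correlation). Their median log2 fold change was -1.27, or -0.99 with genes at 0 counts set to their bound. Of 14 B lineage genes 3 were lower (10 adjusted over the list alone, and 1 higher), among them Cd24a, 2.54-fold lower (camera adjusted p = 0.000107, adjusted p = 0.134 with an estimated correlation). Erythroid and megakaryocyte genes had 1 higher of 15 (3 adjusted over the list alone) and a median of 1.12 (camera adjusted p = 0.000557, adjusted p = 0.302 with an estimated correlation).

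T lineage genes had 3 higher and 2 lower of 29 (5 and 3 adjusted over the list alone, camera adjusted p = 0.101, adjusted p = 0.654 with an estimated correlation). Wnt response genes had 1 higher, Axin2, and 1 lower, Cd44, of 10 (5 and 2 adjusted over the list alone, camera adjusted p = 0.278, adjusted p = 0.451 with an estimated correlation). The progenitor list held 4 higher, with Gfi1b 2.74-fold, and 4 lower, with Erg 1.88-fold (camera adjusted p = 0.716, adjusted p = 0.873 with an estimated correlation). For mitochondrially encoded genes 0 of 8 were called over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 0.00195, adjusted p = 0.405 with an estimated correlation), with mt-Nd1 at 577 ± 10.5 against 465 ± 6.65 CPM. Of 25 interferon response genes 4 were lower, with Ifit1 1.48-fold (camera adjusted p = 0.44, adjusted p = 0.842 with an estimated correlation). In proliferation (26 genes), stroma (20), dendritic (15) and gamma-delta T (14) lists 0 members were called, and the dendritic median of -0.02 had the opposite sign to its test (camera adjusted p = 0.455, 0.388, 0.926 and 0.919, adjusted p = 0.828, 0.877, 0.983 and 0.949 with an estimated correlation). In total 262 genes were higher and 858 lower among 15010 tested, 325 by at least 2-fold. With any 1 of the 4 replicates left out fewer than these 1120 genes were called. The genes named here as changed kept their calls, but they are a part of the rule's picks, and other picks lost theirs.

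**Figure D4:**
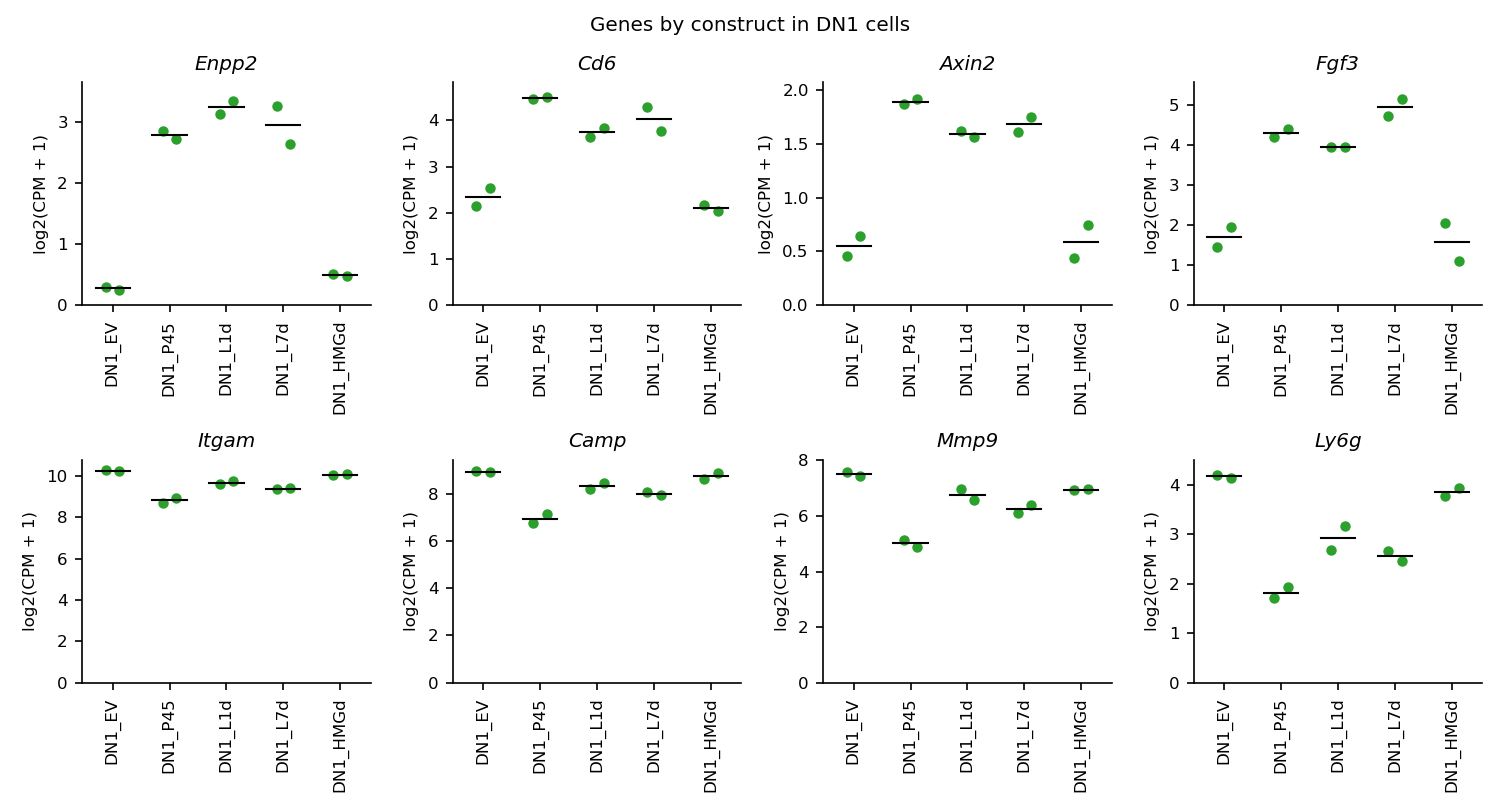
Each panel shows 1 gene in DN1 cells as log2(CPM + 1) on the vertical axis for the 5 constructs on the horizontal axis; points are summed replicates and black lines are means of 2. Enpp2 is at 0.211 CPM with EV and at 5.91, 8.51 and 6.89 CPM with P45, L1d and L7d, and Itgam is at 1219 CPM with EV against 451 CPM with P45.

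Whether the loss of L1 alters the wild-type effect in DN1 cells was asked by comparing L1d with P45. Stfa1, a stefin, rose 3.29-fold from 11.5 ± 1.28 to 37.7 ± 0.874 CPM (SD, n = 2, SE 0.19, adjusted p = 0.00137). Mmp9 rose 3.44-fold to 108 ± 20.9, Prg2, the major basic protein of eosinophils, 2.96-fold to 119 ± 0.301, Camp 2.59-fold to 318 ± 38.1 and Itgam 1.82-fold to 819 ± 45.1. Of 36 myeloid genes 5 were higher, 0 lower and 31 not called (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.76e-05, adjusted p = 0.523 with an estimated correlation). Of 23 mast cell and basophil genes Alox5 and Hdc were higher, 1.95-fold and 1.74-fold, the same 2 adjusted over the list alone, with a list median of 0.8 (camera adjusted p = 6e-07, adjusted p = 0.272 with an estimated correlation). Of 20 stroma genes 0 were called, with a median of 0.86 (camera adjusted p = 0.00109, adjusted p = 0.587 with an estimated correlation). T lineage genes had 2 higher of 29, Ets1 and Ikzf3, with a median of 0 and a mean of -0.5 (camera adjusted p = 0.336, adjusted p = 0.798 with an estimated correlation). Cd5 was 2.4 ± 0.472 and Cd6 12.4 ± 1.39 CPM with L1d, both not called.

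In total 183 genes were higher and 17 lower, and the total of 200 was 4 without L1d replicate 2, 6 without P45 replicate 1, 43 without L1d replicate 1 and 51 without P45 replicate 2. Of 28 called genes that the naming rule picked, Vcan and Stfa1 kept their call in all 4 cases. Itgam had adjusted p = 0.108 without L1d replicate 2 and 0.155 without P45 replicate 1. Mmp9 had adjusted p = 0.0679 to 0.131 with each of the 4 left out. For Camp, the adjusted p was 0.102 without L1d replicate 2 and 0.146 without P45 replicate 1, and for Prg2 it was 0.0578 to 0.168. Without 1 of those same replicates Alox5 had adjusted p = 0.0679 or 0.0918 and Hdc up to 0.124. Against EV, L1d had 30 genes higher and 41 lower. Enpp2 rose 39-fold to 8.51 ± 0.988 CPM (SD, n = 2) and Nucb2, a calcium-binding protein, fell 3.14-fold from 139 ± 7.49 (SE 0.1, adjusted p = 4.04e-07). That total of 71 was 160 with DESeq2 and 13 to 36 with 1 replicate left out, where more genes were higher than lower in each case (8 and 5 without EV replicate 1, 26 and 10 without EV replicate 2, 13 and 2 without L1d replicate 1, 12 and 5 without L1d replicate 2). The change with L1d was also set against that of P45 with 20 simulations of unchanged groups. The covariance less the simulated one was 56.1% of the P45 variance of 0.229 less the simulated 0.0971, with r = 0.64 across genes (0.49 simulated) and a covariance of 0.127 (0.0529 simulated).

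The same question for L7 was answered by L7d in DN1 cells. Against EV, Enpp2 rose 31.4-fold, Fgf3 13.4-fold to 30.1 ± 6.28 CPM, Axin2 4.76-fold, Cd6 3.84-fold and the T cell kinase Prkcq 3.62-fold, while Prss34 fell 7.86-fold, Ly6g 3.48-fold and Itgam 1.83-fold to 665 ± 20.2 CPM (SD, n = 2). Myeloid genes had 0 higher and 9 lower of 36 (11 lower adjusted over the list alone, camera adjusted p = 3.3e-08, adjusted p = 0.389 with an estimated correlation). Erythroid and megakaryocyte genes had 4 higher of 15 (13 adjusted over the list alone, camera adjusted p = 1.04e-10, adjusted p = 0.134 with an estimated correlation). T lineage genes had 4 higher of 29 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0386, adjusted p = 0.576 with an estimated correlation). There were 255 genes higher and 495 lower, and the total of 750 was 182 to 414 with 1 of the 4 replicates left out. Against P45, Gpc1, a glypican, was the 1 gene called, 1.62-fold higher at 89.1 ± 1.92 CPM (adjusted p = 0.0378), against 847 genes at an unadjusted p under 0.05 and 35 with DESeq2. With edgeR 0 were called with any 1 replicate left out, where Gpc1 had adjusted p = 0.293 to 1. For the L7d change the same share was 82.3% of that difference, with r = 0.78 (0.55 simulated) and a covariance of 0.161 (0.0528 simulated), and shared 138 higher and 466 lower genes with it, where independent lists would share 4.45 and 28.3. L1d against L7d called 7 genes higher and 2 lower, with Stfa1 4.33-fold higher (adjusted p = 0.000228), against 1105 at an unadjusted p under 0.05 and 53 with DESeq2. In that comparison 1 was left with any 1 replicate left out.

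Whether DNA binding is needed in DN1 cells was asked with HMGd. Against EV, Tcf7 itself was the 1 gene called, while 1143 had an unadjusted p under 0.05, DESeq2 called 13 and leaving out HMGd replicate 1 gave 66. Against P45, 5 genes named above as raised by P45 were lower, Enpp2 14.2-fold at 0.406 ± 0.0267 CPM (SD, n = 2, SE 0.41, adjusted p = 6.56e-05), Fgf3 8.17-fold, Cd6 6.48-fold, Axin2 5.43-fold and Cd5 5.05-fold. Both comparisons use the same P45 replicates, so P45 values that are high by chance would favour both results. Myeloid genes had 9 higher and 1 lower of 36 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.587 with an estimated correlation). Itgam was 2.37-fold higher at 1069 ± 42.8 CPM and Ly6g 5.24-fold higher. Mast cell and basophil genes had 11 higher of 23 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.41e-12, adjusted p = 0.174 with an estimated correlation). Alox5 was 2.24-fold and Hdc 1.93-fold higher, and the list's median was 1.99, or 1.2 with genes at 0 counts set to their bound. Cpa3 was 6-fold higher, at 61.8 CPM in HMGd replicate 2 against 24.3 CPM in replicate 1. The T lineage list had 1 higher and 2 lower of 29 (2 and 3 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.551 with an estimated correlation). In total 556 genes were higher and 173 lower, and the total of 729 was 235 without P45 replicate 1, 366 without HMGd replicate 2 and 370 without P45 replicate 2. For the HMGd change the covariance less the simulated one was 15.3% of the P45 variance less the simulated variance, with r = 0.39 (0.49 simulated) and a covariance of 0.0728 (0.0526 simulated). Tcf7, which both constructs add, was among these genes and was the 1 called gene shared with P45. Part of this share is thus the constructs' own RNA. Part of what constructs shared in DN1 cells may come from the EV controls, which were not split because each part would hold 1 replicate.

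Whether L1 matters once cells reach the DN2 stage was read from L1d against P45 in DN2 cells. Bcl11b stood at 1.0 ± 1.16 against 18.9 ± 4.38 CPM (SD, n = 2, 19-fold, SE 0.79, adjusted p = 0.00439) and Thy1, a T cell surface marker, at 1.47 ± 0.866 against 24.4 ± 8.09 (16.6-fold, SE 0.53, adjusted p = 0.000232). Cd247, a chain of the T cell receptor complex, was 13.5-fold lower. The kinase Lck was at 19.4 ± 1.29 against 69.1 ± 1.21 (3.56-fold, SE 0.3, adjusted p = 0.00122) and Il2ra at 410 ± 53.3 against 1229.8 ± 66.9 (3-fold, SE 0.21, adjusted p = 0.000232). Cd3g had 0 counts with L1d against 8.35 ± 6.56 CPM, which makes it at least 88-fold lower over a floor of 3 counts in the group (a bound that covers counting error only). Its adjusted p of 0.00806 was 0.0511 without L1d replicate 2 and 0.0551 without P45 replicate 1. Of 29 T lineage genes 0 were higher, 17 lower and 12 not called (22 lower adjusted over the list alone), with a median of -1.57 (camera adjusted p = 2.72e-14, adjusted p = 0.159 with an estimated correlation). Col1a1, a stromal collagen, stood at 114 CPM in L1d replicate 2 against 14.4 CPM in replicate 1.

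Genes of other lineages were among those higher with L1d. Ccr7, a chemokine receptor of dendritic and T cells, rose from 21.4 ± 0.892 to 98.7 ± 0.144 CPM (SD, n = 2, 4.6-fold, SE 0.12, adjusted p = 7.29e-08). Il12b, a subunit of interleukin 12, rose 8.56-fold, Zbtb46, a transcription factor of dendritic cells, 6.86-fold and Spib 6.61-fold. Of 15 dendritic genes 8 were higher and 0 lower (9 higher adjusted over the list alone, camera adjusted p = 1.27e-11, adjusted p = 0.17 with an estimated correlation). Of 36 myeloid genes 26 were higher and 0 lower (32 higher adjusted over the list alone, camera adjusted p = 9.16e-23, adjusted p = 0.179 with an estimated correlation). Mpo, myeloperoxidase, was at 3294 ± 721 against 1286 ± 44.8 CPM, Itgam at 102 ± 27 against 42.3 ± 1.2 and Cebpe 2.53-fold higher. Of 23 mast cell and basophil genes 16 were higher and 0 lower (19 higher adjusted over the list alone, camera adjusted p = 7.85e-16, adjusted p = 0.143 with an estimated correlation). Among them Ms4a2, a chain of the IgE receptor, was at 8.23 ± 2 against 1.15 ± 0.277 CPM, with Il1rl1 3.3-fold and Hdc 2.32-fold higher. Erythroid and megakaryocyte genes had 6 higher of 15 (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000709, adjusted p = 0.302 with an estimated correlation), with Car2 2.2-fold higher.

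In DN2 cells with L1d, Notch1 fell 1.79-fold from 193 ± 1.17 CPM (SD, n = 2), and 2 of 12 Notch response genes were lower (3 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.17 with an estimated correlation). Gamma-delta T cell genes had 2 higher and 5 lower of 14 (2 and 5 adjusted over the list alone), with Cd163l1 35.9-fold and Tcrg-C2 12-fold lower (camera adjusted p = 0.00594, adjusted p = 0.21 with an estimated correlation). Progenitor genes had 8 higher of 24 (10 higher and 2 lower adjusted over the list alone), with Lmo2 1.86-fold and Hlf 3.09-fold higher (camera adjusted p = 0.0186, adjusted p = 0.375 with an estimated correlation). Of 22 early stress genes 10 were higher (12 adjusted over the list alone), with Gadd45b 2.46-fold and Dusp1 1.61-fold (camera adjusted p = 6.61e-06, adjusted p = 0.199 with an estimated correlation). Of 26 proliferation genes 7 were lower (8 adjusted over the list alone, camera adjusted p = 6.4e-06, adjusted p = 0.252 with an estimated correlation). Mcm6, 1.22-fold lower, had adjusted p = 0.101 without L1d replicate 2, 0.133 without P45 replicate 1 and 0.0507 without P45 replicate 2. Of 25 interferon response genes 7 were higher, with Gbp2 1.57-fold (8 adjusted over the list alone, camera adjusted p = 0.00285, adjusted p = 0.468 with an estimated correlation). Of 8 mitochondrially encoded genes 4 were higher (7 adjusted over the list alone, camera adjusted p = 0.000762, adjusted p = 0.375 with an estimated correlation). Among them mt-Co1 stood at 1909.5 ± 196 against 1427.7 ± 77 CPM, with adjusted p = 0.166 without L1d replicate 2, 0.0518 without P45 replicate 1 and 0.137 without P45 replicate 2.

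Lists of innate lymphoid (16 genes), natural killer (17), stroma (20), Wnt response (10), later T cell (19), p53 response (17) and B lineage (14) genes had camera adjusted p = 0.904, 0.513, 0.318, 0.287, 0.603, 0.305 and 0.278 (adjusted p = 0.93, 0.717, 0.86, 0.464, 0.823, 0.464 and 0.486 with an estimated correlation). The B lineage median of 0.08 and the innate lymphoid median of -0.01 had the opposite sign to their tests. In total 1209 genes were higher and 421 lower in DN2 cells with L1d, 664 by at least 2-fold. The total of 1630 was 528 without P45 replicate 1, 569 without L1d replicate 2 and 799 without P45 replicate 2, and 662 in a fit of the DN2 libraries alone.

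**Figure D5:**
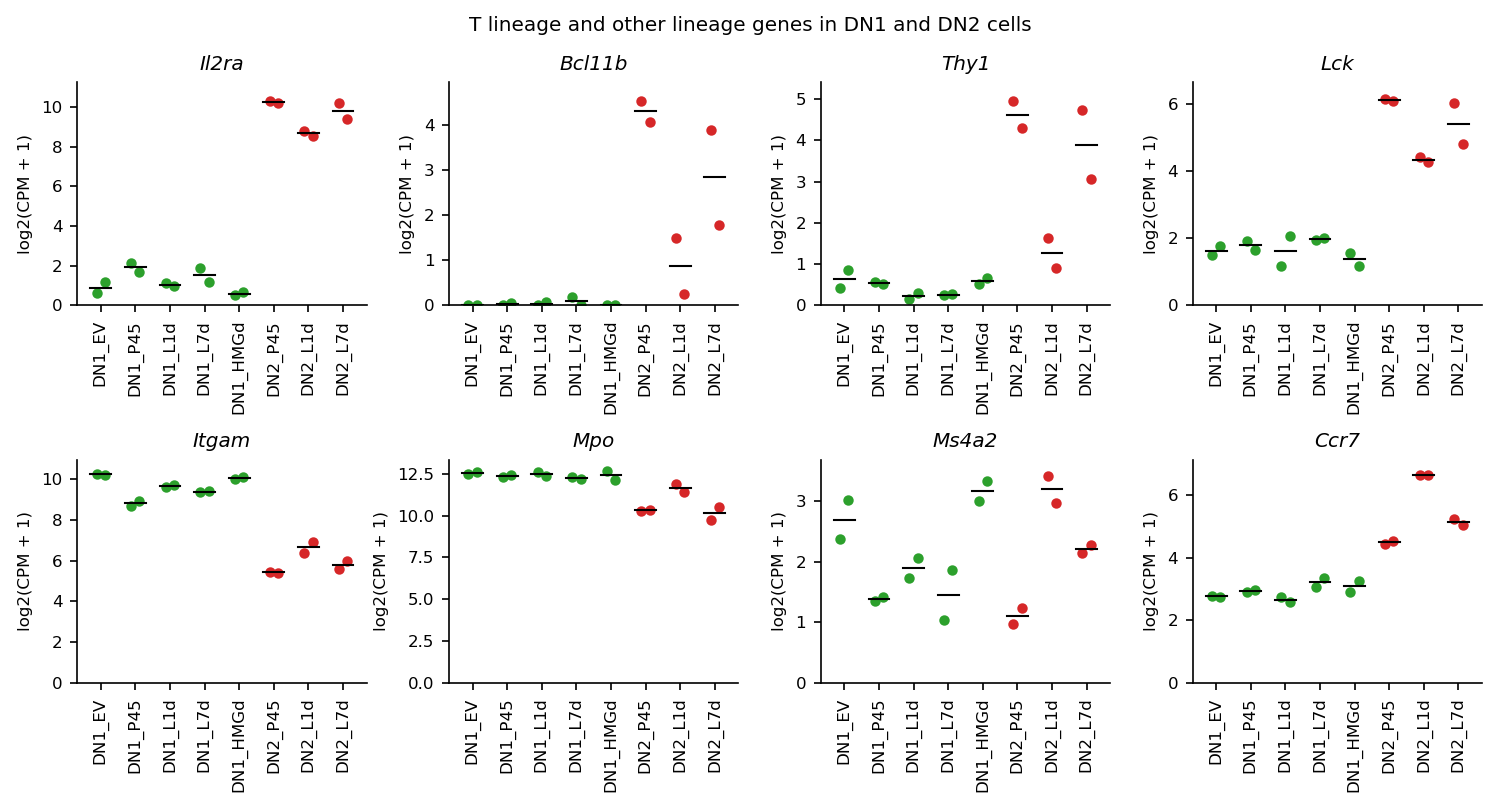
Each panel shows 1 gene as log2(CPM + 1) on the vertical axis for the 8 primary groups on the horizontal axis, DN1 in green and DN2 in red; points are summed replicates and black lines are means of 2. In DN2 cells Bcl11b and Thy1 are lower with L1d (1.0 and 1.47 CPM) than with P45 (18.9 and 24.4 CPM), and Ccr7 and Ms4a2 are higher (98.7 and 8.23 against 21.4 and 1.15 CPM).

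L7d against P45 asked the same of L7 in DN2 cells. Ccl22, a chemokine, was 2.41-fold higher at 16.5 ± 2.2 CPM and Gata1, an erythroid and mast cell transcription factor, 3.13-fold higher at 14.6 ± 3.43, while Vcan, a proteoglycan, was 1.76-fold lower at 164 ± 11.6 (SD, n = 2, adjusted p = 0.017, 0.0488 and 0.017). Mast cell and basophil genes had 2 higher of 23 (12 adjusted over the list alone, camera adjusted p = 8.4e-15, adjusted p = 0.159 with an estimated correlation). Dendritic genes had 1 higher of 15 (8 adjusted over the list alone, camera adjusted p = 1.42e-08, adjusted p = 0.199 with an estimated correlation). Erythroid and megakaryocyte genes had 2 higher of 15 (7 adjusted over the list alone, camera adjusted p = 1.16e-10, adjusted p = 0.134 with an estimated correlation). Of 29 T lineage genes 0 were called, with a median of -0.38 (camera adjusted p = 0.00387, adjusted p = 0.467 with an estimated correlation). Bcl11b was 2.44 CPM in L7d replicate 2 and 13.8 CPM in replicate 1. There were 36 genes higher and 8 lower, 1130 with an unadjusted p under 0.05 and 120 called by DESeq2. With the replicate number as a block 176 were called, 147 higher and 29 lower. The total of 44 was 0 without P45 replicate 1, 2 without P45 replicate 2 and 6 without L7d replicate 2 (and 3 in a fit of the DN2 libraries alone). In those 3 cases with a replicate left out, Ccl22 had adjusted p = 0.429, 0.0683 and 0.0804, Gata1 0.555, 0.205 and 0.327, and Vcan 0.192, 0.0617 and 0.078.

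The constructs L1d and L7d were also compared with each other in DN2 cells. With L1d, Thy1 was 11.1-fold lower (adjusted p = 0.00152) and Il2ra 2.27-fold lower, while Ccr7 was 2.9-fold, Clec7a 3.21-fold and Cebpe 2.57-fold higher. These are a part of the rule's picks, and other picks, Bcl11b among them, lost their call when 1 replicate was left out. T lineage genes had 0 higher and 9 lower of 29 (19 lower adjusted over the list alone, camera adjusted p = 2.55e-12, adjusted p = 0.175 with an estimated correlation). Myeloid genes had 28 higher and 0 lower of 36 (33 higher adjusted over the list alone, camera adjusted p = 2.73e-39, adjusted p = 0.134 with an estimated correlation). Of 20 stroma genes 1 was higher, Thbs1 (13 adjusted over the list alone, camera adjusted p = 0.000267, adjusted p = 0.549 with an estimated correlation). In total 709 genes were higher and 163 lower, and the total of 872 was 186 without L7d replicate 1, 343 without L1d replicate 2 and 156 in a fit of the DN2 libraries alone.

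The step from DN1 to DN2 was described within each construct. With P45, Il2ra rose from 2.81 ± 0.86 to 1229.8 ± 66.9 CPM (SD, n = 2, 455-fold, SE 0.31, adjusted p = 4.31e-11) and Gzma, a granzyme, 109-fold to 144 ± 17.6. The T cell receptor constant gene Trbc1 rose 54.4-fold, Tox 32.7-fold, Lck 28.5-fold and the Notch target Dtx1 12.7-fold. Trdc had 0 counts in DN1 cells and was at least 254-fold higher in DN2, and Cd3g was at least 150-fold higher. Bcl11b went from 0.0151 ± 0.0213 to 18.9 ± 4.38 CPM. Of 29 T lineage genes 22 were higher and 3 lower (23 and 3 adjusted over the list alone, camera adjusted p = 4.61e-08, adjusted p = 0.233 with an estimated correlation). Of 12 Notch response genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 1.56e-05, adjusted p = 0.134 with an estimated correlation). Gamma-delta T cell genes had 10 higher of 14 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.14e-06, adjusted p = 0.134 with an estimated correlation). Innate lymphoid genes had 12 higher and 3 lower of 16, with Pdcd1 27.2-fold higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.00462, adjusted p = 0.18 with an estimated correlation). Later T cell genes had 9 higher and 1 lower of 19, with Arpp21 22.4-fold higher (10 and 1 adjusted over the list alone, camera adjusted p = 0.000908, adjusted p = 0.233 with an estimated correlation).

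Myeloid genes went the other way, with 0 higher, 34 lower and 2 not called of 36 (34 lower adjusted over the list alone, camera adjusted p = 7.6e-30, adjusted p = 0.168 with an estimated correlation). Itgam fell 10.6-fold and Cebpe 9.84-fold, and among granulocyte genes outside the list Chil3 fell 103-fold from 824 ± 121 CPM and Prg2 167-fold. Interferon response genes had 1 higher and 17 lower of 25, with Zbp1 2.18-fold lower (1 and 17 adjusted over the list alone, camera adjusted p = 0.000223, adjusted p = 0.377 with an estimated correlation). Mast cell and basophil genes parted, with 11 higher and 7 lower of 23 (camera adjusted p = 0.822, adjusted p = 0.949 with an estimated correlation): Cpa3 rose 16.2-fold to 114 ± 4.59 CPM and Hdc fell 4.28-fold. Calls were 3095 higher and 3398 lower with P45, 3022 and 2956 with L1d and 2923 and 3278 with L7d. With L1d, Il2ra rose 401-fold and Gzma 45.8-fold. T lineage genes had 15 higher and 3 lower of 29 (camera adjusted p = 0.00818, adjusted p = 0.501 with an estimated correlation) and dendritic genes had 13 higher of 15 (camera adjusted p = 3.74e-07, adjusted p = 0.233 with an estimated correlation). With L7d, Il2ra rose 475-fold and T lineage genes had 22 higher and 2 lower of 29 (camera adjusted p = 1.05e-06, adjusted p = 0.3 with an estimated correlation).

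Whether the effect of losing L1 differed between the stages was tested as an interaction. Relative to DN1 cells, the L1d against P45 change in DN2 cells was more positive for Ccr7 (by 5.83-fold, SE 0.2, adjusted p = 2.67e-05), Ccl22 (7.78-fold, SE 0.31, adjusted p = 0.000204), Gbp2 (1.6-fold, SE 0.09, adjusted p = 0.00176) and Clec7a (3.64-fold, SE 0.3, adjusted p = 0.00686). It was more negative for Cd24a (by 2.78-fold, SE 0.22, adjusted p = 0.00446). These genes are a part of the rule's picks, and other picks lost their call when 1 replicate was left out. Of 15 dendritic genes 6 were called with a more positive change (9 adjusted over the list alone, camera adjusted p = 3.07e-15, adjusted p = 0.134 with an estimated correlation). Of 36 myeloid genes 2 were (22 adjusted over the list alone, camera adjusted p = 9.14e-14, adjusted p = 0.283 with an estimated correlation). Of 29 T lineage genes 0 were called, with 3 more negative adjusted over the list alone and a median of -1.19 (camera adjusted p = 9.81e-06, adjusted p = 0.302 with an estimated correlation). Of these 29 genes 6 had 0 counts in DN1 cells with L1d or with P45, so their change there is poorly measured. These values thus do not show whether the effect on T lineage genes differs by stage. In total 182 genes were more positive and 55 more negative, against 2089 at an unadjusted p under 0.05. The total of 237 was 565 without DN2 L1d replicate 1 and 58 to 107 without each of the other 7 replicates.

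The cell line and the primary cells share no library, and their calls were compared over 10440 genes tested in both. Fisher's exact test, used for the overlaps, takes genes as independent, which they are not. Nor does it allow for genes that are easier to call in both systems. Excesses occurred in the same and in opposite directions, so its p-values do not measure a shared effect of the constructs. For wild-type TCF-1 against EV, 114 genes were lower in both the cell line and DN1 cells, where independent lists would share 61.9 (Fisher's exact test, 2-sided, adjusted p = 3.65e-10). Further, 18 were higher in both against 18.1 by chance (adjusted p = 1), 39 were lower in the line and higher in DN1 cells against 17.9 (adjusted p = 8.4e-06), and 39 went the opposite way against 62.6 (adjusted p = 0.00199). Genes that P45 lowered in DN1 cells were, as a set, lower with WT in the line (camera adjusted p = 0.00968, adjusted p = 0.00205 with an estimated correlation) and higher than with WT with each of the 4 segment deletions. For DL1, DL2, DL6 and DL7 their medians against WT were 0.06, 0.1, 0.1 and 0.09 (camera adjusted p = 0.0124, 0.000911, 0.0116 and 0.0108, adjusted p = 0.00205, 0.00133, 0.00205 and 0.00251 with an estimated correlation), and for DHMG -0.01 (camera adjusted p = 0.762, adjusted p = 0.484 with an estimated correlation). Against EV, the median of this lowered set was -0.1 with DHMG (camera adjusted p = 0.00372, adjusted p = 0.00154 with an estimated correlation) and -0.08 with WT. Those that P45 raised were also higher than with WT with the 4 segment deletions, with medians of 0.11, 0.09, 0.13 and 0.12 (camera adjusted p = 0.000189, 0.000911, 0.00014 and 0.000265, adjusted p = 0.0148, 0.0289, 0.0148 and 0.018 with an estimated correlation), and for DHMG the median was 0.03 (camera adjusted p = 0.327, adjusted p = 0.483 with an estimated correlation). These comparisons all share the 2 WT libraries. With WT against EV, the median of the raised set was -0.12 (camera adjusted p = 0.0537, adjusted p = 0.166 with an estimated correlation, fry adjusted p = 0.00214). For the loss of L1, 47 genes were higher in the line and lower in DN2 cells against 23.2 by chance (adjusted p = 1.18e-05), 44 were higher in both against 30.7 (adjusted p = 0.0328) and 26 lower in both against 13.9 (adjusted p = 0.0047). In DN1 cells 12 were higher in both against 6.2 (Fisher's exact test, adjusted p = 0.0554). As sets, genes higher and lower with DL1 had medians of -0.03 and -0.12 for L1d against P45 in DN2 cells (camera adjusted p = 0.0503 and 0.00014, adjusted p = 0.483 and 0.388 with an estimated correlation). In DN1 cells their medians were 0.01 and -0.05 (camera adjusted p = 0.762 and 0.0607, adjusted p = 0.901 and 0.648 with an estimated correlation). Bcl11b and Il2ra are examples of opposite direction, higher with DL1 than with WT in the line and lower with L1d than with P45 in DN2 cells.

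Genome positions (build GRCm38, GENCODE M21) were as follows: Tcf7 chr11:52252371-52283014, Ighm chr12:113418558-113422730, Ndrg1 chr15:66929318-66969640, Nfib chr4:82290173-82705750, Cpa3 chr3:20215620-20242181, Itgae chr11:73090583-73147446, Ahnak chr19:8989284-9076914, Itgam chr7:128062640-128118491, Mmp9 chr2:164940780-164955850, Cd6 chr19:10789341-10830058, Axin2 chr11:108920349-108950783, Enpp2 chr15:54838901-54952892, Il2ra chr2:11642807-11693193, Bcl11b chr12:107910403-108003602, Thy1 chr9:44043384-44048579, Ccr7 chr11:99144196-99155077, Mpo chr11:87793581-87804413 and Ms4a2 chr19:11615523-11623719.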

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

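The tests of explanations in this part were all chosen after the results they address had been seen, while the test of the stage difference was fixed before the data were examined.

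Effects of the same construct were compared between stages or systems by a test of the difference itself. Between DN2 and DN1 cells, the change with L1d against P45 differed in 237 genes. Over the 10440 genes tested in both systems, the cell line and DN1 cells differed in 199 genes for the loss of L1 (131 with a more positive change in the line and 68 more negative), in 1494 for the loss of L7, in 1389 for wild type against EV and in 744 for the HMG deletion against EV. The cell line and DN2 cells differed in 717 genes for the loss of L1 and in 947 for the loss of L7. The counts between systems came from a fit with the same dispersion per gene for both. The common biological coefficient of variation was 9.2% in primary cells and 4.48% in the line. Those counts are thus no measure of how many genes differ. The systems also differ in cell type, time after transduction and the level of Tcf7 with EV, so such differences cannot be assigned to the constructs alone.

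In DN2 cells with L1d, T lineage genes such as Bcl11b and Thy1 were lower and myeloid, mast cell and dendritic genes such as Mpo, Ms4a2 and Ccr7 were higher than with P45. The sort gated on CD25. DN1-type cells left in it would need to be 71.9% of the cells at the median of 17 called T lineage falls. The smallest called fall would need 19.6%. By contrast, 20 abundant DN1 genes imply at most 5.99%, and 41 of the 49 called higher myeloid, mast and dendritic genes need a larger share than that (23 of 49 were higher in these DN2 cells than in DN1 cells with L1d). These 20 genes include members of the myeloid list such as S100a9, Ngp, Ltf and Camp. Changes too small to be called were left out, so the smallest needed share partly reflects the threshold. For the called genes, the values argue against carry-over of the average mix of DN1 cells. DN1 cells poor in the 20 abundant genes are not limited by them. Stromal cells in L1d replicate 2, where Col1a1 was highest among DN2 replicates although the sort gated on CD45, are argued against by the 29 measured T lineage genes, with a median log2 fold change of -1.47 without that replicate (27 below 0) and -1.57 with both, and by 73 myeloid, mast and dendritic genes, with 1.01 without it (67 above 0) and 1.17 with both. A lower amount of the construct's RNA is argued against by Tcf7 itself, with a log2 fold change of 0.23 (SE 0.09, edgeR adjusted p = 0.141). An effect of the construct on the cells stays open and untested. So do DN1 cells poor in the 20 abundant genes, and cells of another lineage within the CD25-high gate. These bulk libraries do not resolve such cells.

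In the cell line, genes known to respond to low oxygen or to act in glycolysis differed between constructs, with Ndrg1 at 58.6 CPM with EV, 3.76 with WT, 1.82 with DL1, 0.152 with DHMG, 199 with DL2, 158 with DL6 and 160 with DL7. A list of 29 such genes, of which 26 were measured, was written after the data were seen, and its camera adjusted p with an estimated correlation was 6.55e-07 for DL2 against WT and at most 0.0201 in the other cell line comparisons. That test held Ndrg1 and Bnip3, whose changes had been seen, so its p-values partly restate them. Without these 2 genes, 22 of 24 were higher and 0 lower for DL2 against WT. Lowering by TCF-1 as the only cause is argued against by 15 of 24 members other than Ndrg1 and Bnip3 that were higher with DL7 than with EV. Oxygen or density of the cultures at harvest cannot be told apart from an effect of the constructs, since 21 of the same 24 were higher with DL7 than with WT, and the labels give neither density nor culture. The comparison of constructs in the line could thus hold culture effects in these genes.

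The HMG-deleted construct gave 1871 calls against EV in the cell line and 1 in DN1 cells. Less precise values in DN1 cells stay open. The 744 genes called for the difference itself came from a fit with the same dispersion per gene for both systems. The common biological coefficient of variation was 9.2% in primary cells and 4.48% in the line, so that fit cannot decide this. DHMG cultures from a diverged sub-line are a candidate explanation, since all 3 measured Y chromosome genes were low in them, Kdm5d at 7.85%, Ddx3y at 8.66% and Uty at 26.9% of the lowest other group. An effect of the truncated protein in the line stays open, as does a separate handling of these libraries, in which ribosomal RNA genes took 32% of counted reads, and no biological explanation was tested.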

How the results depend on the processing

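The counts that ignore strand were chosen after the data were seen, and all other alternatives were fixed before the data were examined. Below, a count of called genes is taken as unchanged when it stays within 1.5 times.

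Tcf7 levels, and the direction of the genes named by the rule, held under most alternatives. With counts that ignore strand, all 26 counts of calls stayed within 1.5 times, and of 1287 gene values 1248 kept direction and side of the threshold. In that setting 26 lost a call, 8 gained one and 3 changed sign while not called. Cebpb in DL7 against WT went from a log2 fold change of -0.46 to 0.21, and mt-Nd6 in DHMG against WT from -0.74 to 0.13, where reads of the opposite strand are added by construction. RLE scaling kept 25 of 26 counts, with 5 genes for L1d against L7d in DN1 cells where TMM gave 9, and moved the median of all genes by at most 0.013 on the log2 scale. Fits without DHMG kept 9 of 9 counts, and the fit of EV, WT and DHMG alone kept 2 of 2.

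DESeq2 kept 10 of 26 counts. In the cell line it called fewer genes, with 1757 for WT against EV, 604 for DL1, 286 for DL2, 95 for DL6, 161 for DL7 and 1198 for DHMG against EV, and 799 for DL2, 1426 for DL6, 2184 for DL7 and 1020 for DHMG against WT. In 6 primary comparisons it called over 1.5 times as many, with 160 for L1d against EV, 13 for HMGd against EV, 35 for L7d against P45 and 53 for L1d against L7d in DN1 cells, 120 for L7d against P45 in DN2 cells and 443 for the interaction. Of the gene values, 102 lost and 49 gained a call under DESeq2. For these counts, the cause was not tested.

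Without a filter on low counts 17 of 26 counts stayed within 1.5 times. The others rose, to 379 for L1d against EV, 180 for HMGd against EV, 474 for L1d, 211 for L7d and 1232 for HMGd against P45 and 219 for L1d against L7d in DN1 cells, to 447 for L7d against P45 and 1543 for L1d against L7d in DN2 cells, and to 988 for the interaction. The cause was not tested.

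Groups share only a number in their replicate labels. In the cell line the correlation of same-numbered deviations was -0.07 to 0.09, with 0 of 21 group pairs over 0.1, and in primary cells -0.04 to 0.48, with 21 of 28 over 0.1. With the replicate block 20 of 26 counts stayed within 1.5 times, while L1d against EV gave 157, HMGd against EV 3, L7d against P45 12 and L1d against L7d 24 in DN1 cells, L7d against P45 176 in DN2 cells, and the interaction 516. Of the gene values, 1 lost and 50 gained a call with the block.

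With each T library as a replicate the counts were larger by construction, since the spread within a B replicate is smaller. They were 2778 for P45, 743 for L1d, 2315 for L7d and 368 for HMGd against EV, 1126 for L1d, 446 for L7d and 2127 for HMGd against P45 and 648 for L1d against L7d in DN1 cells. In DN2 cells they were 3522 for L1d and 807 for L7d against P45 and 2365 for L1d against L7d, and the interaction had 1685. In fits of the same stage alone, DN1 cells gave 183 genes for L1d against EV, 7 for HMGd against EV, 431 for L1d against P45, 60 for L7d against P45 and 65 for L1d against L7d, and DN2 cells 662 for L1d against P45, 3 for L7d against P45 and 156 for L1d against L7d. These fits hold fewer samples, and the cause was not tested further.

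With each replicate left out in turn, of 5312 gene values 4473 kept direction and side of the threshold and 43 changed sign while not called, 758 lost a call, 38 gained one, and 0 reversed while called. Counts in the cell line against EV ranged from 1631 to 1770 for WT, 466 to 1541 for DL1, 235 to 277 for DL2, 50 to 62 for DL6, 95 to 135 for DL7 and 1067 to 1226 for DHMG. Against WT they ranged from 532 to 1590 for DL1, 596 to 763 for DL2, 1376 to 1492 for DL6, 2152 to 2465 for DL7 and 835 to 1026 for DHMG. In DN1 cells against EV the ranges were 500 to 678 for P45, 13 to 36 for L1d, 182 to 414 for L7d and 1 to 66 for HMGd. Against P45 they were 4 to 51 for L1d, 0 to 0 for L7d and 235 to 997 for HMGd, and L1d against L7d gave 1 in each case. In DN2 cells L1d against P45 ranged from 528 to 1975, L7d against P45 from 0 to 66 and L1d against L7d from 186 to 1160. DN2 against DN1 ranged from 5007 to 5360 with P45, 4134 to 5534 with L1d and 4680 to 5256 with L7d, and the interaction from 58 to 565.

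Camera with an estimated correlation called 0 of the 19 planned lists in any comparison, against a preset-correlation call in 19 comparisons for mitochondrial genes and 16 for T lineage genes, so those calls rest on the preset value. Fry, which tests whether a list's genes move on balance, called erythroid genes in 4 comparisons (camera 10), mast cell genes in 5 (12), mitochondrial genes in 12 (19), myeloid genes in 7 (14), stroma genes in 0 (4), Wnt response genes in 13 (1) and p53 response genes in 12 (2). Fry asks a different question from camera by construction. As a limit of depth and replicate number together, in the simulated DN1 comparison of L1d with P45 over 15010 genes, 62% of genes changed 2-fold were called.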

Other observations

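The genes in this part were measured in the tests fixed before the data were examined, except Uty, Gm42418 and the level of Bnip3 with DHMG, which were chosen after their values were seen.

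Surface markers of the sort gates were also read as RNA in DN2 against DN1 cells. Il2ra, which encodes CD25, followed the gate with every construct. Kit, the stem cell factor receptor, was 2.7-fold higher in DN2 than in DN1 cells with P45, at 272 ± 16.6 against 101 ± 10.9 CPM (SD, n = 2, edgeR adjusted p = 7.61e-09), and 2.81-fold higher with L1d, although the gates in the labels name DN2 cells as c-Kit low. Cd44, an adhesion molecule, was 2.13-fold lower in DN2 cells with P45 and 2.08-fold lower with L1d, as the gates in the protocol give it. Cd27, a costimulatory receptor, was 5.88-fold higher and Zbtb16, a factor of innate-like T cells, 4.8-fold higher in DN2 cells with P45. Spi1, which encodes the myeloid factor PU.1, was 2.06-fold lower at 147 ± 2.34 against 303 ± 2.22 CPM.

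In the cell line, Y chromosome genes were present in all groups but low with DHMG. Kdm5d stood at 0.652 ± 0.922 CPM, Ddx3y at 1.43 ± 0.552 and Uty at 1.48 ± 1.23 with DHMG (SD, n = 2). Bnip3, a gene of the low oxygen response, was 2.89 ± 1.5 CPM with DHMG. The gene Gm42418, which overlaps ribosomal RNA, took 10.78% and 10.84% of the counted reads in the 2 DHMG libraries.

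The spread between libraries differed with their labels. The dispersion index, which would be near 1 for counting error alone, had a median of 1.57 over 7 pairs of cell line replicates, 1.87 over 40 pairs of T libraries of the same B replicate and 2.9 over 61 pairs of T libraries from different B replicates. Cell line replicates thus differed about as little as T libraries of the same B replicate.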
